A study of Caenorhabditis elegans with 2 samples.

How the data were processed

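ChIP-seq peak lists of 2 biological replicates of 1 group were used, per the labels: young adult worms of the strain with tagged UNC-62, collected at 4 days. The labels name a possible control experiment, and per the deposited README texts each replicate list was derived from the alignment of that replicate and a control, the pooled list from both alignments and a control, and the IDR-thresholded list from the pooled and both replicate lists. The aligner, peak caller and their versions are not given in the sources used here. The 8 deposited lists were on the builds ce11 and ce10, and only ce11 coordinates are printed, 1-based. The signal column of the lists as deposited gives the strength of a peak from the authors' peak caller, and it was used to describe, rank or filter peaks within a list. It was also compared between the replicate lists by correlation and ratio, on scales that the sources do not state to be shared. The other column used, −log10 of the q-value as deposited by the authors, reached its upper limit of 3.40 in all 843 IDR-thresholded peaks, so it could not rank them. Replicate lists are relaxed and hold background regions by design. Read counts and depth per replicate are unknown, so intervals given for shares of peaks cover counting of peaks only, and the depth could differ between the replicates.

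Summits were taken as the deposited summit position. Genes and transcript starts were those of Ensembl release 115 for WBcel235, which is ce11, and sequence was that of the same assembly. Promoter windows ran from 1000 bp upstream to 200 bp downstream of the 5' end of each protein-coding transcript. A peak in the windows of several genes counted for each. Signal of an IDR-thresholded peak in a replicate was that of the strongest overlapping peak of that replicate. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

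Nulls for overlap and location rotated the positions along each chromosome by 1 random offset per chromosome and draw, with 100000 draws. The 21 gene lists, their tests, the promoter windows, the motif words and the alternatives were fixed before the data were examined. Lists were tested with Fisher's exact test, two-sided, against all other nuclear protein-coding genes, with Benjamini-Hochberg adjustment over the 21 lists. Odds ratios are sample odds ratios, with exact conditional 95% intervals. Location classes and motif words were adjusted over their own families. Summits per chromosome were compared with length by a chi-square statistic over 100000 multinomial draws. With 1 group no test between conditions was possible, and the tests of overlap and of signal ratios between the replicates ran over peaks. P-values over peaks or genes measure these lists, not the spread between worms, since peaks and genes are not replicates.

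Named genes followed a rule fixed before the data were examined: the gene with the nearest start for each of the 20 strongest IDR-thresholded peaks, every vitellogenin and TALE or Hox gene, at most 4 members with the strongest promoter peaks of every other list, and unc-62 and unc-119. The list of 20 nuclear peaks was added after the values were seen, and a part of it is named.

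The tests were tested on simulated data. With 800 random summits and 2000 rotations, the number of 100 runs past 0.05 was 3 for promoters, 5 for at least 1 gene list after adjustment, 4 for the motif, 6 for replicate overlap and 7 for chromosomes. With 80 summits moved to promoters, 10 moved to ribosomal protein promoters, or TGACAG planted in 80 windows, all 100 runs of each passed. The random summits were independent and spread evenly over the nuclear chromosomes. The real ones gathered at promoters, so these runs do not cover that gathering or clusters of peaks. Alternatives covered other promoter windows, the 421 strongest peaks, each replicate alone (the 843 strongest peaks of the other left out), other overlap rules, other backgrounds and tests, and the ce10 lists. Removal of mitochondrial peaks, 1 gene per peak region, unc-62 left out of the lists, and the correlation over the whole pooled list were added after seeing the data, as were the location classes other than promoters, the chi-square over nuclear chromosomes and the shares of chromosome X in other lists.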

Results

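Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where UNC-62 was bound in whole Caenorhabditis elegans young adults at 4 days, with both sexes pooled. UNC-62 is a homeodomain transcription factor of the Meis and Homothorax class, known for its roles in development and in the control of yolk genes. The worms were of strain OP600, which carries the unc-119 allele ed3 and a transgene with unc-62 fused to TY1, EGFP and FLAG tags together with an unc-119 marker. The label for the antibody names unc-62 and the description names the EGFP fusion, so it is open whether the peaks reflect the tagged protein alone or native UNC-62 too. The series holds 1 group with 2 biological replicates and no second condition, so the design asks where the factor was bound and how well the replicates match, and allows no comparison between conditions. Sequenced fragments spanned 150 to 350 bp per the labels. The lists give positions and strengths of peaks, and the read depth behind them is unknown. The relaxed list of replicate 1 held 30000 peaks, that of replicate 2 held 28092, and the list called on the pooled reads held 19023, all on the ce11 build. On ce10 the list of replicate 1 also held 30000 peaks. Whether a limit on its length set its lowest signal values was not tested.

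The list that passed the irreproducible discovery rate (IDR) threshold held 843 peaks, of which 815 lay on the nuclear chromosomes and 28 on the mitochondrial chromosome. The authors' signal value ran from 31.2 to 514 with a median of 40.2, and the common peak width was 320 bp. The 12 narrower nuclear peaks had a median signal of 116, against 39.6 for nuclear peaks of the common width. All 12 ranked among the 20 strongest nuclear peaks. They include the 6 nuclear peaks described next and those near cki-2, pno-1 and tmem-184 named further below. The cause was not tested. Of the 20 strongest peaks, 14 were mitochondrial. The strongest lay in the coding sequence of ND5 (MtDNA, 13030 to 13317, signal 514), a subunit of respiratory complex I, and the next had the start of CYTB, the cytochrome b gene, nearest to it (MtDNA, 4628 to 4864, signal 439). The start of ND5 was also nearest to 2 more of the 14, and the starts of ND3, ATP6, ND4, ND4L, COX2, ND6, ND1, COX3 and 2 genes without a matched symbol were nearest to 1 peak each. The other 6 of these 20 peaks were nuclear, and their distances are given from the nearest protein-coding start, negative upstream. They lay at -1168 bp from casc-3 (I, 13337194 to 13337423, signal 241), between srh-70 and ceh-99 (II, 12518964 to 12519099, signal 137), at -1380 bp from M106.2 (II, 10851273 to 10851501, signal 136) and at -159 bp from cdc-48.1 (II, 10563501 to 10563619, signal 129). The remaining ones lay at -5963 bp from unc-62 itself (V, 4491466 to 4491565, intergenic, signal 127) and in an intron, 1349 bp from the start of fbxl-5 (V, 7744189 to 7744337, signal 118). CDC-48.1 is an AAA ATPase that extracts ubiquitylated proteins, and srh-70 and ceh-99 encode a predicted chemoreceptor and a homeobox protein. All 6 were found in both replicates, with signal values of 106 and 148 at the casc-3 peak and 43.6 and 83.9 at the cdc-48.1 peak in replicates 1 and 2.

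Because mitochondrial peaks filled most of the top of the list, the 20 strongest nuclear peaks were also listed, a choice made after the values were seen. Beyond the 6 above, they included peaks upstream of ceh-20, the worm Pbx-type partner of UNC-62 (III, 6978977 to 6979296, at -747 bp, signal 107), and at -1370 bp from cki-2, which encodes a cyclin-dependent kinase inhibitor, within another annotated gene (II, 7815102 to 7815191, signal 114). Others lay at the start of vrp-1 (IV, 3012436 to 3012755, signal 112), in an intron 1266 bp from the start of pno-1 (II, 9741524 to 9741664, signal 109), at -250 bp from tmem-184 (X, 14707089 to 14707195, signal 106) and in an intron 1932 bp from the start of dnj-20 (II, 9622084 to 9622403, signal 102).

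The replicates shared many of their strongest peaks. Of the 843 strongest peaks of replicate 1, 417 (49.5%, exact 95% interval 46.0 to 52.9%) overlapped 1 of the 843 strongest of replicate 2 by at least 1 bp, against a mean of 29.6 when replicate 1 peaks were rotated along their chromosomes. No rotation of 100000 reached the observed number (one-sided permutation p = 1e-05, the smallest these draws can give). The IDR-thresholded list was derived from these lists, so its recovery in them is no separate evidence of agreement. Recovery was 835 of 843 peaks in replicate 1 and 843 of 843 in replicate 2. The list is labelled optimal, and a place on it did not require an overlapping peak in replicate 1. Among the 843 strongest peaks of each replicate, 64.7% of the IDR-thresholded peaks were recovered in replicate 1 and 79.1% in replicate 2. Over 835 peaks Spearman's rho of the signal values was 0.19 (bootstrap 95% interval 0.11 to 0.26) and Pearson's r of their log2 values was 0.43. Without the mitochondrial peaks rho was 0.11 and r was 0.19. Over the 8445 peaks of the pooled relaxed list found in both replicates rho was 0.39. The IDR threshold restricts the list, which can narrow the range of signal and lower rho, and this was not tested. Not every peak was strong in both replicates. For example, a peak within unc-62 had 4.08 in replicate 1, whose relaxed list began at 3.19, and 29.1 in replicate 2. These correlations run across peaks, which are not independent replicates. Replicate 2 had the higher signal value at 754 of the 835 peaks, with a median ratio of replicate 1 to replicate 2 of 0.534, on scales that the sources do not state to be shared.

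**Figure D1:**
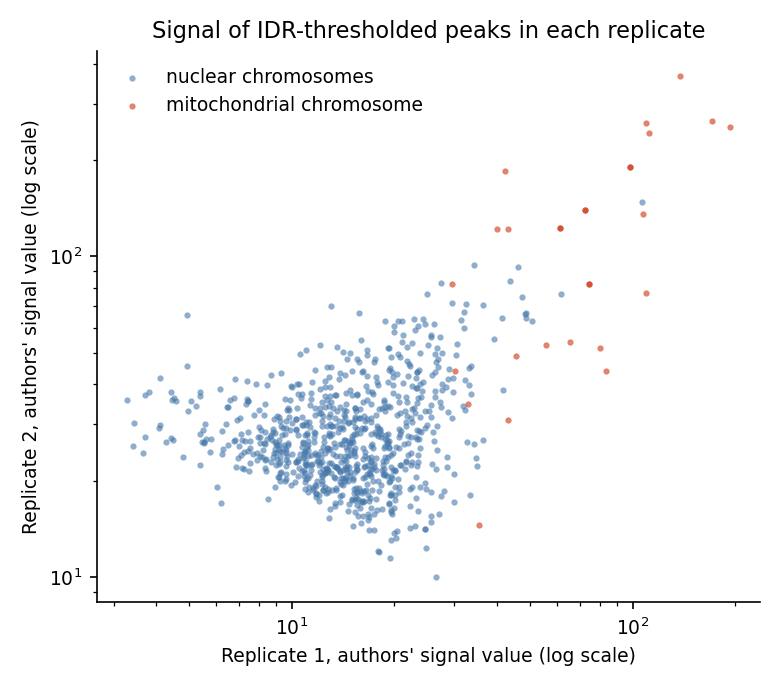
Signal value of each IDR-thresholded peak in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), one point per peak found in both replicates (835), blue for nuclear and red for mitochondrial peaks. Mitochondrial peaks reach the upper right corner, and the nuclear cloud shows the low rank correlation of 0.11.

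Summits of the nuclear peaks gathered upstream of genes and avoided coding sequence. Of all 843 summits, 446 (52.9%, exact 95% interval 49.5 to 56.3%) lay within the promoter window, from 1000 bp upstream to 200 bp downstream of an annotated protein-coding transcript start, against 27.5% of rotated positions (two-sided permutation p = 2e-05, the smallest these draws can give). The weakest 843 peaks of the pooled relaxed list reached 29.3%. Among the 815 nuclear summits, 426 (52.3%) were in promoter windows, 218 (26.7%) were intergenic against 22.3% of rotated positions (permutation test, adjusted p = 0.00854), and 133 (16.3%) were in introns against 27.1%. Only 9 summits (1.10%) were in coding sequence against 18.8% of rotated positions, and 7 (0.859%) were in the 3' UTR against 2.43% (permutation test, adjusted p = 0.00252). These classes other than promoters were added after the peaks had been seen. The values for promoters, introns and coding sequence each had an adjusted permutation p of 4.7e-05. Relative to the nearest start, 271 summits (33.3%) lay 0 to 500 bp upstream and 108 (13.3%) lay 500 bp to 1 kb upstream. Annotated starts of many worm genes are trans-splice sites downstream of the true start, so distances to transcription itself are not resolved here.

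**Figure D2:**
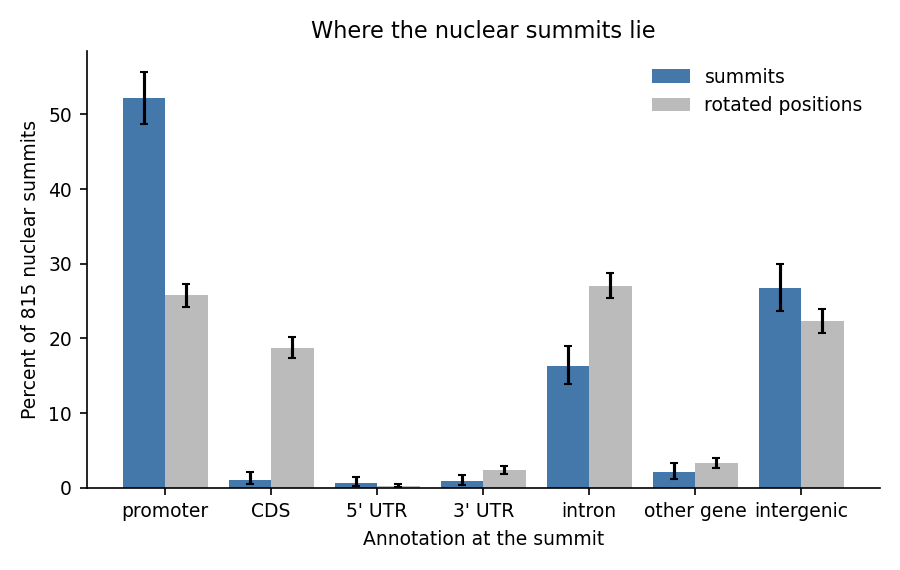
Percent of the 815 nuclear summits (blue, bars with exact 95% intervals) and of rotated positions (grey, mean with the SD over rotations) by annotation at the summit, each summit counted once with promoter windows taking precedence. Promoter windows hold 52.3% of summits against 25.8% of rotated positions, and coding sequence holds 1.10% against 18.8%.

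Some yolk protein genes and homeodomain genes of the TALE type carried promoter peaks, and both of their lists passed the exact test but not the rotation test. In all, 487 of the 19973 nuclear protein-coding genes (2.44%) had a summit in the promoter window. Of the 6 vitellogenins, which encode the yolk proteins made in the adult intestine, vit-6 (IV, 8261157 to 8266459) and vit-2 (X, 5101042 to 5106169) had a promoter peak. The peak of vit-6 lay 140 bp upstream with signal 73.0 (26.8 and 45.1 in replicates 1 and 2), and that of vit-2 lay 127 bp upstream with signal 63.1 (16.6 and 49.4). The other members, vit-1, vit-3, vit-4 and vit-5, had no IDR-thresholded promoter peak and had relaxed ones, with pooled signal values of 21.9, 27.6, 22.1 and 23.3. With the 843 strongest peaks of replicate 1 alone, vit-1 (15.9) and vit-4 (16.1) joined vit-2 and vit-6, giving 4 of 6 members (odds ratio 80.3). With those of replicate 2 alone it was 2 of 6 (odds ratio 20.7): vit-1 had no relaxed promoter peak there and vit-4 had one of 5.68. Vitellogenin genes are close paralogs, so reads that map to several of them could be lost or split, and their differences are uncertain. The list passed Fisher's exact test with an odds ratio of 20.1 (95% interval 1.81 to 140) and an adjusted p of 0.0324. The call ended under the rotation test, a permutation test which keeps neighbouring genes together (adjusted p = 0.361). The list also did not pass among genes with a relaxed promoter peak (odds ratio 6.35, exact test, adjusted p = 0.198). That background comes from the same ChIP signal, so its result decides little. Over all alternatives its adjusted p from exact and permutation tests ran from 3.6e-05 to 0.361.

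Of the 11 TALE and Hox genes, 4 had a promoter peak, and all 4 were of the TALE type: ceh-20 (signal 107), unc-62 (79.1), ceh-60 (50.9) and ceh-40 (31.7). CEH-60, like CEH-20 and CEH-40, is a Pbx-type homeodomain protein, known as a regulator of yolk production. The 2 replicates gave 27.3 and 82.6 at ceh-20 and 26.6 and 24.8 at ceh-60. With the 843 strongest peaks of replicate 1 alone 3 of 11 members had a peak, and with those of replicate 2 alone 4 of 11. Among these, ceh-40 was present with neither replicate alone, and the Hox gene ceh-13 (21.3 in replicate 2) was present with replicate 2 alone. The other TALE gene, psa-3, had no peak there in the IDR-thresholded or pooled relaxed list. None of the Hox genes had an IDR-thresholded promoter peak: ceh-13, lin-39 and mab-5 had relaxed ones with pooled signal values of 25.7, 10.2 and 9.92, and egl-5, php-3 and nob-1 had none in the pooled relaxed list. The list passed Fisher's exact test (odds ratio 23.05, 95% interval 4.93 to 90.9, adjusted p = 0.000704). Its member unc-62 is also carried by the transgene. Without it, 3 of 10 genes had a peak (odds ratio 17.3, 95% interval 2.87 to 75.9, exact test, adjusted p = 0.0106), an alternative chosen after seeing the data. The whole list did not pass with the rotation (permutation) test (adjusted p = 0.144) or with the window of 500 bp upstream to 100 bp downstream, which lost ceh-20 and ceh-60 (exact test, adjusted p = 0.0519), and over all alternatives the exact or permutation adjusted p ran from 0.000221 to 0.144.

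By count, genes of the translation machinery had the most members with a promoter peak among the lists that passed. The smaller lists of TALE and Hox genes (36.4%) and vitellogenins (33.3%) had larger shares. Of 78 ribosomal protein genes, 17 (21.8%) had a promoter peak against 2.36% of other genes (odds ratio 11.5, 95% interval 6.25 to 20.2, Fisher's exact test, adjusted p = 9.7e-11), and the call held in the rotation test and the other alternatives (exact or permutation adjusted p from 1.9e-16 to 0.00889). Its size depended on how peaks were given to genes: 9 of 78 members had a peak when each peak went to the nearest start alone (odds ratio 3.59) and 9 of 78 with 1 gene per peak region (odds ratio 6.44). It also differed by replicate, with 22 of 78 for the strongest peaks of replicate 1 alone (odds ratio 16.3) and 12 of 78 for those of replicate 2 alone (odds ratio 7.66). The strongest were rpl-12 (signal 66.3), rpl-3 (63.3), rpl-15 (61.2) and rps-19 (52.1), the last with the start of another gene nearer to its peak. Replicate 1 exceeded replicate 2 at rpl-12 (36.5 and 26.7) and rpl-3 (35.0 and 22.2) and was lower at rpl-15 (24.2 and 38.0) and rps-19 (20.6 and 29.0). Of the 16 peaks at ribosomal protein promoters 4 were higher in replicate 1, as were 37 of 406 other promoter peaks found in both replicates. In all, 0 of the 16 peaks at ribosomal protein promoters had TGACAG within 50 bp of the summit. Cytochrome P450 and glucuronosyltransferase genes, which modify lipophilic compounds, had promoter peaks at 10 of 141 members (odds ratio 3.10, 95% interval 1.44 to 5.93, Fisher's exact test, adjusted p = 0.0128), led by ugt-41 (61.3), ugt-49 (57.6) and ugt-64 (43.5). This call ended with replicate 1 alone (exact test, adjusted p = 0.701), in the rotation (permutation) test (adjusted p = 0.144), and with the 421 strongest peaks, the nearest start or the relaxed background. Over all alternatives the exact or permutation adjusted p ran from 0.0103 to 0.701. Proteasome and vacuolar ATPase genes had 5 of 53 members with a peak (odds ratio 4.201, 95% interval 1.299 to 10.6, Fisher's exact test, adjusted p = 0.0324), and 4 of these 5 were subunits of the proton pump: vha-12 (45.6), vha-8 (36.3), vha-1 (33.7) and vha-15 (32.04). The other was rpn-3, a proteasome subunit, named after its value was seen. This call was absent with either replicate alone (exact test, adjusted p = 0.249 without replicate 1 and 0.294 without replicate 2). It also ended in the rotation (permutation) test (adjusted p = 0.144), and in the exact test with the relaxed background (adjusted p = 0.198), the nearest start (0.189), 1 gene per peak region (0.0707) and the 421 strongest peaks (0.737). In that order the odds ratios of these exact tests were 2.55, 2.23, 3.98 and 1.67. Over all alternatives the exact or permutation adjusted p ran from 0.0154 to 0.737.

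Chemoreceptor genes, most of which are expressed in few neurons, had fewer promoter peaks than other genes. Only 7 of 1310 (0.534%) had a peak against 2.57% of other genes (odds ratio 0.204, 95% interval 0.0812 to 0.424, Fisher's exact test, adjusted p = 8.4e-07). The rotation (permutation) test did not reach the threshold (adjusted p = 0.0672), nor did the exact test among genes with a relaxed promoter peak (odds ratio 0.440, adjusted p = 0.118). That background holds 205 of the 1310 genes and comes from the same ChIP signal, so its result decides little. The lowest adjusted p over the alternatives was 2.3e-10 (exact test). The strongest of the 7 were srh-70 (137), srz-62 (65.1), srh-83 (61.3) and srh-2 (59.97), and 2 of these shared a summit with a neighbour, srh-70 with ceh-99 and srh-83 with ugt-41.

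The remaining 15 lists did not pass the adjusted exact test. Regulators of yolk production had 2 of 12 members with a promoter peak (exact test, adjusted p = 0.0744), ceh-60 and alg-1, the latter an Argonaute protein of the microRNA pathway (signal 32.1). The lipid metabolism list had 3 of 26 (odds ratio 5.25, exact test, adjusted p = 0.0649), the receptor gene nhr-49 (44.4), dgat-2 (33.5) and the desaturase gene fat-6 (32.3). The peaks of dgat-2 and fat-6 lay nearer to the start of another gene. With 1 gene per peak region the lipid list had 1 of 26 (odds ratio 1.94), and with the nearest start 3 of 26 (odds ratio 3.57). With replicate 1 alone that list had 1 of 26 (odds ratio 1.595), and with replicate 2 alone 2 of 26 (odds ratio 3.45). The ceh- homeobox family had 5 of 63 (exact test, adjusted p = 0.0559), with ceh-99, ceh-20, ceh-38 (63.4) and ceh-60 the strongest. Nuclear hormone receptors had 10 of 269 (exact test, adjusted p = 0.284), led by nhr-35 (81.0), nhr-1 (70.7) and nhr-71 (51.8). By the same exact test, intestinal markers had 1 of 19, the microvillar actin gene act-5 (33.6, adjusted p = 0.605), neuronal markers 1 of 28, mec-3 (54.1, adjusted p = 0.687), germline and oocyte genes 1 of 22, cgh-1 (32.2, adjusted p = 0.629), and insulin, stress and lifespan genes 1 of 30, rheb-1 (44.2, adjusted p = 0.687). The peaks of cgh-1 and rheb-1 also lay nearer to the start of another gene. C-type lectins had 2 of 240, clec-72 (38.3) and clec-150 (33.7), with an odds ratio of 0.334 and an exact test adjusted p of 0.259. With replicate 2 alone they had 5 of 240 (odds ratio 0.876), and with replicate 1 alone 1 of 240 (odds ratio 0.165). None of the 156 col- collagens had a peak (exact test p = 0.0354, adjusted p = 0.0744), and neither did the lists of 23 dpy-type collagens, 14 hypodermal genes, 21 body wall muscle genes, 12 pharynx genes and 19 Wnt pathway genes (adjusted p = 1 each).

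**Figure D3:**
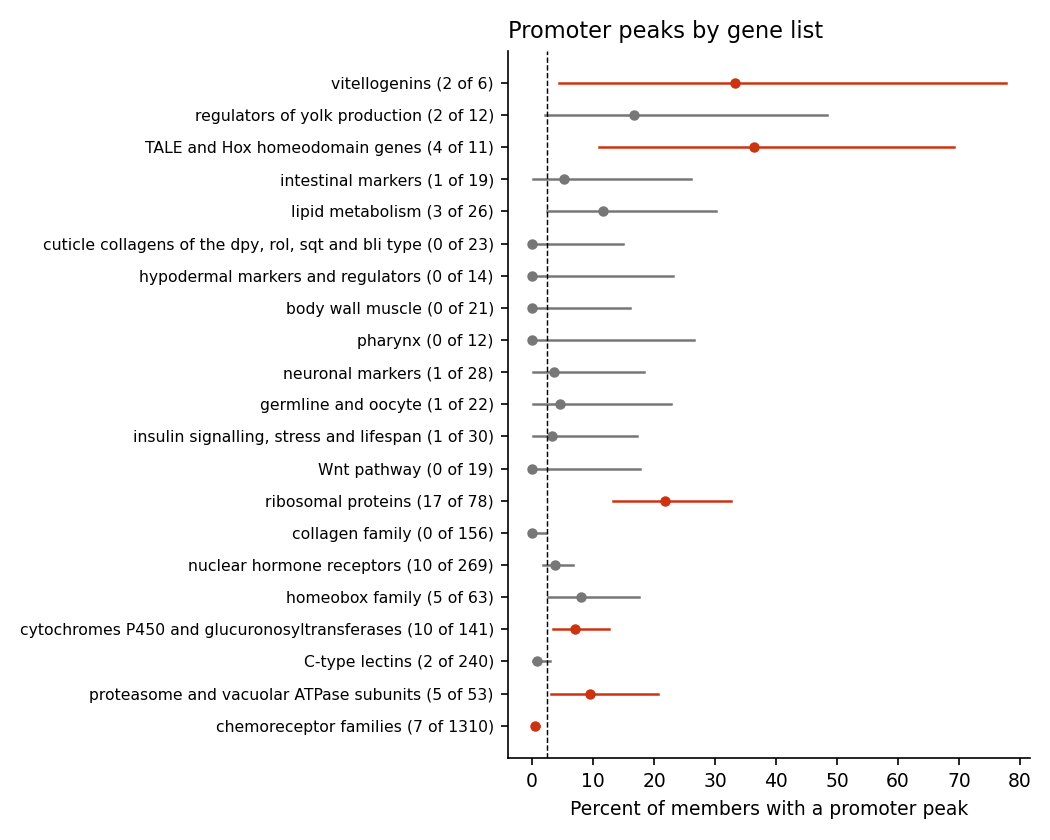
Percent of the members of each list with a promoter peak (horizontal axis, points) with exact 95% intervals (lines), red where the adjusted Fisher p was under 0.05 and grey elsewhere, with the count of members beside each name. The dashed line is the share over all 19973 genes (2.44%), and ribosomal proteins stand at 21.8%.

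The sequence word TGACAG, the known core site of Meis-type homeodomains, was centred on the summits. It lay within 50 bp of the summit at 180 of 843 peaks (21.4%, exact 95% interval 18.6 to 24.3%) and in 27 (3.20%) of flanking windows of the same size 400 bp away (exact McNemar test, two-sided, p = 9.0e-31). The weakest 843 relaxed peaks had it at 4.03% of summits (Fisher's exact test p = 2.5e-28). Among the 180 orderings of its bases TGACAG ranked 1, with an excess of 153 windows at the centre against 70 for the next ordering, and among all 2080 words of 6 bases it ranked 2, after TTGACA, which overlaps it (26.3% against 7.24%). The composite of Pbx and Meis sites, TGATTGACAG, was rare, in 11 windows against 1 (exact McNemar p = 0.00635, adjusted p = 0.00952). It contains TGACAG, so this is no separate evidence for the composite. The first 6 bases of the composite, TGATTG, were in 110 central windows against 45 flanks (exact McNemar test, adjusted p = 3.0e-06). That word ranked 30 among the 2080. The Pbx and Hox composite TGATNNAT was not centred (8.54% against 8.78%, exact McNemar p = 0.931). TGATAA, a site of GATA factors such as those of the intestine, was present at 27.8% against 10.1% (exact McNemar test, adjusted p = 2.4e-20), and GAGAG at 30.7% against 11.4% (adjusted p = 1.8e-23). The forkhead site TGTTTAC reached 3.08% against 1.54% (exact McNemar test, adjusted p = 0.0639). Such differences were common, since 234 of all 2080 words were more frequent at the centre and 169 less frequent after adjustment. A difference alone therefore does not single out a word. By the size of the excess, TGATAA ranked 3 among the 2080, directly after TGACAG. GAGAGA, which contains GAGAG, ranked 5. Central windows of the nuclear peaks were richer in G and C (41.8%) than flanks (35.5%).

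**Figure D4:**
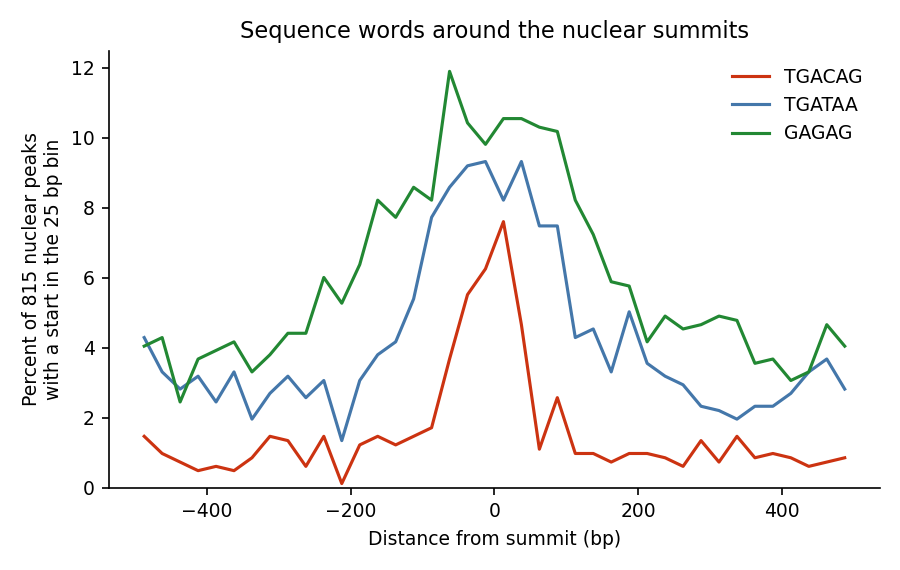
Percent of 815 nuclear peaks with the start of TGACAG (red), TGATAA (blue) or GAGAG (green) on either strand in each bin of 25 bp, by distance from the summit in bp. TGACAG rises in the bins next to the summit, and the other 2 words form broader rises.

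Chromosome X held a larger share of the peaks than of the genome length. Over all chromosomes the peaks departed from chromosome length (chi-square 6766, multinomial simulation p = 1e-05, the smallest these draws can give). That value was set largely by 28 mitochondrial peaks where 0.116 would fall by length. Among the 815 nuclear peaks the departure remained (chi-square 61.3, multinomial simulation p = 1e-05, the smallest these draws can give). The draws take summits as independent and do not keep clusters of peaks. X held 218 (26.7%, exact 95% interval 23.7 to 29.9%) against 17.7% of the nuclear length, I held 88 where 123 would fall, and IV held 107 where 142 would fall, single chromosomes not being tested on their own. On X the strongest nuclear promoter peaks of the fixed lists were those of nhr-35, nhr-1 and vit-2. The share on X was 26.8% for the strongest peaks of replicate 2 and 22.97% for those of replicate 1. With replicate 1 alone the nuclear chi-square fell to 26.0 (multinomial simulation p = 0.00019). The share on X was 18.98% for the weakest relaxed peaks, below that of the IDR-thresholded list (Fisher's exact test p = 0.000176, a comparison added after the values were seen). Against the same weakest peaks, the strongest of replicate 1 gave p = 0.0465 (Fisher's exact test). The whole pooled relaxed list had 20.4% on X and also departed from length (nuclear chi-square 146, multinomial simulation p = 1e-05), so a departure was not confined to the strong peaks.

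The unc-62 gene had a high density of peaks. The gene (V, 4497461 to 4511449) and the 20 kb on each side held 8 IDR-thresholded peaks, or 0.148 per kb (exact Poisson 95% interval 0.0640 to 0.292), and no other of the 19973 protein-coding genes had a higher density in such a region. With 5 kb on each side it held 5 peaks, or 0.208 per kb, at the 99.85 percentile of genes. Of the 8 peaks, 5 lay in the gene body. The strongest of them was at an internal start of unc-62 (4499364 to 4499683, signal 79.1, 36 bp downstream of that start) and had TGACAG at its summit. A cluster of 4 more lay from 4505895 to 4508146 around a further internal start: 1 in an intron, 2 in its promoter window and 1 in a 5' UTR, with signal values of 33.6 to 62.9 and no TGACAG within 50 bp of their summits. The replicates differed at these peaks: the first had 13.1 in replicate 1 and 70.2 in replicate 2, while the peak at 4506648 to 4506967 had 29.8 and 20.96. In the relaxed lists the region held 39 peaks in replicate 1 (percentile 99.96 among genes) and 35 in replicate 2 (percentile 99.88). At unc-119 (III, 10902641 to 10908935) there was no IDR-thresholded peak within 20 kb. Relaxed peaks there stood at the 81.2 percentile in replicate 1 and the 61.7 percentile in replicate 2. The transgene carries unc-62 and an unc-119 marker whose form the labels do not state, and these values do not separate the native copy of unc-62 from the added ones.

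**Figure D5:**
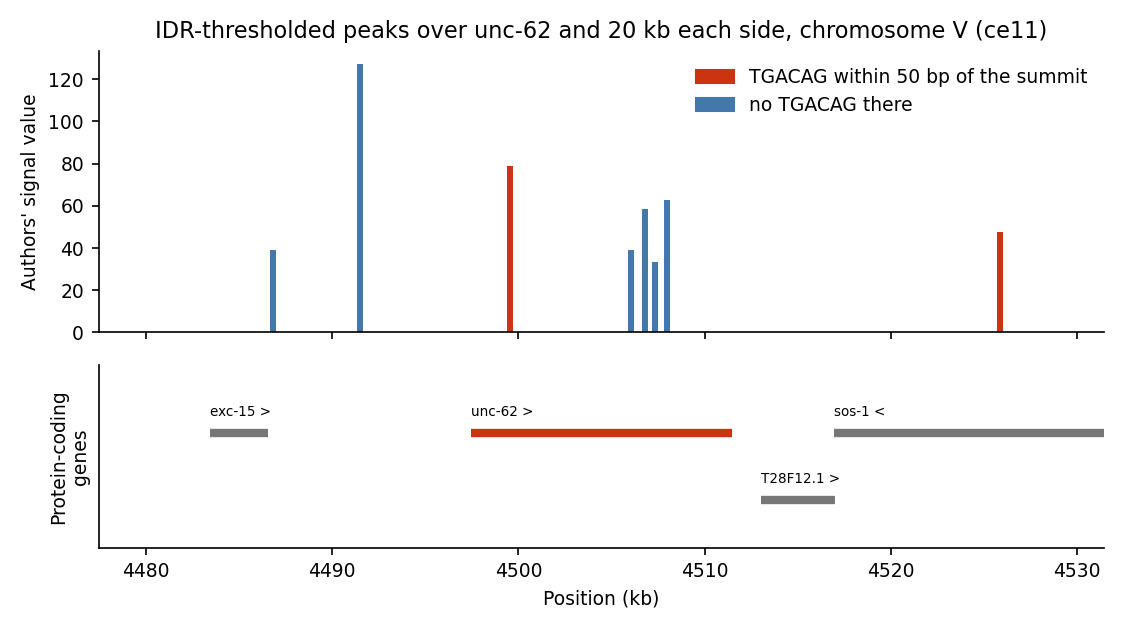
Signal value of the 8 IDR-thresholded peaks (bars at the summits) over unc-62 and 20 kb on each side of it on chromosome V, in kb on ce11, red where TGACAG lies within 50 bp of the summit and blue elsewhere, above the protein-coding genes of the region with arrows for their strand. The highest bar (127) lies upstream of unc-62 and 5 bars lie within it.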

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

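The share of summits at promoters, the overlap of the replicates, the centring of TGACAG and the departure from chromosome length kept their direction and stayed past the threshold in every alternative run, with shares of 37.6 to 68.4% at promoters, 42.9 to 49.4% in overlap and 15.8 to 27.9% with TGACAG. Alternatives without mitochondrial peaks, with 1 gene per peak region, with unc-62 left out of the lists and with the whole pooled list were chosen after seeing the data. On ce10 the IDR-thresholded list held 922 peaks, 892 of them nuclear, against 843 and 815 on ce11. The 421 strongest peaks gave 228 genes with a promoter peak, fewer by construction. The correlation of replicate signals fell to 0.11 without mitochondrial peaks and was 0.39 over the whole pooled relaxed list; the cause was not tested. The number of lists with more promoter peaks, 5 in the main test, was 2 against genes with a relaxed promoter peak, where TALE and Hox genes and ribosomal proteins passed, and 1, ribosomal proteins, in the rotation test. With a replicate left out it was 3 (without replicate 2) and 6 (without replicate 1), and its highest value was 7, with the 2000 bp window; the cause was not tested. Ribosomal proteins passed in each of these. Vitellogenins lost the call only in the rotation test and among genes with a relaxed peak. The regulators of yolk production passed the exact test with the nearest start at any distance (5 of 12 members, adjusted p = 0.000245), with the 2000 bp window and without replicate 1, and over all alternatives the adjusted p reached 0.636. Lists of lipid metabolism (2000 bp window), hypodermal genes (nearest start) and ceh- genes (421 strongest peaks, nearest start, without replicate 1) also passed in those settings, and fewer col- genes than others had a peak with the 2000 bp window and the nearest start, as did fewer C-type lectins with the 2000 bp window (exact test, adjusted p = 0.0400, up to 1 over the alternatives). Of the 37 named list members with a promoter peak, 34 kept one without replicate 1, 26 without replicate 2, 25 with the 421 strongest peaks, 26 with the 500 bp window, 28 with the nearest start and 37 with the 2000 bp window. The replicate overlap and correlation need both replicates, so neither was left out there, and the ce10 list against ce10 chromosome lengths was not run, as no source used here gives them. Depth is unknown, so how far it limits the number of peaks cannot be stated.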

Other observations

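The tests on mitochondrial coverage, the flanks of unc-62, gene families by symbol, noncoding genes, TGACAG by kind of peak and the other replicate ratios were chosen after results were seen. Of 175 families of protein-coding genes that share a symbol prefix and have at least 10 members, 2 passed the adjusted Fisher's exact test, and both were ribosomal: rps (8 of 31 genes, adjusted p = 9.9e-05) and rpl (9 of 47, adjusted p = 0.000148). The next were ugt (7 of 67, exact test, adjusted p = 0.0543), vha (4 of 20, adjusted p = 0.0543) and cox (3 of 15: cox-5A, cox-6B and cox-5B, subunits of cytochrome c oxidase, adjusted p = 0.184). Among 8 classes of noncoding genes and pseudogenes, 3 had more summits and 2 had fewer than rotated positions. Within 200 bp of the gene, 16 nuclear summits lay at snoRNA genes (1.96% against 0.172% of rotated positions, permutation test, adjusted p = 8.0e-05), 10 of them also in a protein-coding promoter window, and 6 lay at snRNA genes (0.736% against 0.0570%, adjusted p = 0.00016). Long intergenic RNA genes had 8 (0.982% against 0.321%, permutation test, adjusted p = 0.0272). The values for tRNA genes (4 summits) and miRNA genes (2 summits) did not pass (permutation test, adjusted p = 0.615 for both), nor did that for rRNA genes (0 summits, adjusted p = 1). The piRNA genes had fewer summits than rotated positions (9, or 1.10%, against 2.58%, permutation test, adjusted p = 0.0213), and so did pseudogenes (4, or 0.491%, against 3.83%, permutation test, adjusted p = 8.0e-05).

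TGACAG was present at 16.7% of summits in the signal quartile of nuclear peaks with the lowest values (204 peaks) and at 27.5% in the quartile with the highest (204 peaks). The difference did not pass adjustment over the 6 comparisons made (odds ratio 1.89, Fisher's exact test p = 0.0119, adjusted p = 0.0714). Promoter peaks and other nuclear peaks had it at 20.2% and 23.9% (exact test, adjusted p = 0.386). Of the 20 strongest nuclear peaks 10 had it, among them those near casc-3, srh-70, M106.2, fbxl-5, cki-2, vrp-1 and tmem-184, and those near cdc-48.1, ceh-20 and the one upstream of unc-62 did not.

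Among the lists that passed, ribosomal proteins had the most members with a promoter peak, and 1 hypothesis was that these promoters gather signal without a Meis-type site. The 16 peaks at these promoters held TGACAG in 0 cases (0%, exact 95% interval 0 to 20.6%), against 86 of 410 other nuclear promoter peaks (20.98%), which is what the hypothesis needs but by a narrow margin, since Fisher's exact test gave p = 0.0507. TGATAA and GAGAG were also less frequent there (6.25% and 12.5%) than at the other promoters (29.0% and 35.4%), untested. Among genes with any relaxed promoter peak the odds ratio of ribosomal proteins fell from 11.5 to 4.61 (95% interval 2.46 to 8.24), but the bound written for it took such a peak as a sign of an open promoter, while it comes from the same ChIP signal, so this value decides nothing. A general pick-up of open promoters, indirect recruitment by another factor and signal that depends on transcription may all remain, and these lists do not separate them.

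The 28 mitochondrial peaks covered 55.9% of that chromosome (7712 of 13794 bp), against 0.258% of the nuclear genome, and the strongest peaks of each replicate covered 57.7% and 55.0% of it. Coverage this broad, in both replicates, is consistent with reads from abundant mitochondrial DNA that the control did not remove, a technical explanation. Binding at TGACAG was argued against by the bound set for it, by a narrow margin. Of 28 mitochondrial summit windows 1 held the word (3.57%, exact 95% interval 0.0904 to 18.3%), below the 21.96% of nuclear windows. The windows lie close together on 1 chromosome, so this interval covers counting only. Most nuclear windows lack the word too, so binding without it is not addressed. No biological explanation was otherwise tested, and the control reads were not analysed here.

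At unc-62 the question was whether added transgene copies may raise the signal. At unc-119 relaxed peaks stood no higher than the 81.2 percentile of genes in either replicate, but the bound written for it assumed the worm's own unc-119 on the transgene, which the labels do not state, so this value decides nothing. For unc-62 alone, relaxed peaks 5 to 20 kb outside the gene body exceeded 98.5% of genes in replicate 1 and 74.6% in replicate 2, or 82.0% with ties counted, on either side of the bound set for it. The first reading, with ties left out, counted against extra copies and was changed to open after its value was seen. Extra copies and binding of UNC-62 to its own gene cannot be told apart, because the replicates differ and the control reads were not analysed here.

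Further hypotheses gave no clear result. TGATAA was present in 33.5% of nuclear summit windows with TGACAG and in 27.04% of those without (odds ratio 1.36, 95% interval 0.934 to 1.97, Fisher's exact test p = 0.0923), so a tie between the words remains open. Peaks with TGACAG were not shown to be relatively stronger in replicate 2. Their median log2 ratio of replicate 1 to replicate 2 signal was -0.92 against -0.90 for other nuclear peaks, a difference of -0.0145 (permutation test p = 0.799, adjusted p over 4 comparisons = 0.799). For ribosomal protein promoters against other promoters the medians were -0.51 and -0.88 (permutation p = 0.0918, adjusted p = 0.367).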
